A study of Mus musculus with 3 samples.

How the data were processed

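Per the labels, total RNA was extracted and sequenced after a standard Illumina library preparation; a selection step is not given in the sources used here. The cells were αTC1-6, a mouse line derived from a glucagon-producing tumour of the pancreatic α cell. They were infected for 16 h with an adenovirus carrying β-galactosidase (β-Gal, the control), NIK or NIK(KA). NIK is the NF-κB-inducing kinase, encoded by Map3k14; in the literature NIK(KA) is a form with a mutated kinase site, which the labels do not spell out. There were 3 libraries, 1 per group, so no difference has a replicate check, and no p-value or standard deviation across replicates is given.

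Per the submitters' processing notes, TopHat2, HTSeq 0.6.1 and the mouse build GRCm38 were used; their roles, the annotation release, the strand setting and the program that made the final values are not given in the sources used here. The deposited values are FPKM, fragments per kilobase of gene length, scaled to the total of counted reads, for 52948 gene IDs in each library. Without a stated strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart. Genes with near-identical copies (the H2 genes, Gbp3, Serpina1a and Serpina1b) are uncertain, since how reads that match several copies were counted is not given. All 3 deposited columns were used and 0 were left out.

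Gene IDs were matched to GENCODE release M21, also on GRCm38, for symbols, gene types and coordinates. Of the IDs, 52489 matched. A further 312 are not Ensembl IDs and have no symbol here, and 135 of these passed the expression filter.

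The FPKM values of each gene were whole multiples of what 1 read is worth in that gene and library. Well-covered genes, at their GENCODE M21 lengths, gave the β-Gal library total behind the values, the same whole number in 2260 genes. The other totals followed from the commonest ratio of values between libraries. The totals were 18629668 reads for β-Gal, 15523580 for NIK and 16652922 for NIK(KA). Whole reads, within 0.001 of a read, were then recovered for 26583 of the 26584 genes detected in at least 1 library. Their sums came to 99.56%, 99.54% and 99.56% of the totals. The gene lengths they imply lay within 1 base of the mean transcript length in GENCODE M21 for 90.8% of genes. Recovery was tested on simulated data of 24851 genes and gave the exact reads for 98.1% of them. The recovered reads were used only for exact intervals and simulations, and not for a count model.

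Levels were compared as differences of log2(FPKM + 1). The pseudocount of 1 understates the difference of low genes. A gene was called higher or lower when that difference was at least 1, or 2-fold, among the 12950 genes with a mean FPKM of at least 1 over the 3 libraries. Map3k14 was left out of every count and list. Ratios of reads per library total carry an exact 95% interval (conditional binomial). These intervals cover counting error only, and reads without molecular identifiers are not independent molecules. Where a library held 0 reads, only the lower end of the exact interval of the ratio is given, as at least so many fold. A count of 0 was taken to allow up to 3 reads, the value put in its place for list ratios.

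Before the data were examined, 22 gene lists with 386 distinct genes, the 2-fold rule, the filter and the alternatives of processing were fixed. For each list with at least 3 members past the filter, the median difference was set against 10000 random lists of the same size matched on mean expression in 20 bins. A list is said to lie above or below the random lists outside their 2.5 and 97.5 percentiles. This describes these libraries and is not a test of the conditions. The genes named are Map3k14, the 10 protein-coding genes with the largest difference in each direction per comparison, up to 4 members of each list past the rule, and a fixed set (Gcg, Pcsk2, Nfkb1, Nfkb2, Relb, Nfkbia, Tnfaip3, Birc3, Ccl2, Cxcl10, Ins2, Sst, Actb and Gapdh, with others that are not reported here). Genes named outside this rule are marked as chosen after their values were seen.

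Libraries that differ by counting error alone were simulated 100 times, with each gene at its pooled rate over the 3 libraries, or over β-Gal and NIK(KA) for the comparison of those. The 2-fold rule was tested on simulated data of the NIK against β-Gal comparison with 12806 genes past the filter. It recovered 44 of 50 genes made 3-fold higher, 50 of 50 made 8-fold higher, 42 of 50 made 3-fold lower and 42 of 50 made 8-fold lower. It also called 64 unchanged genes.

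Alternatives changed the pseudocount (0.1 or 5), the filter (none, or a mean FPKM of at least 5), the scaling (median ratio, upper quartile, or an equal sum per library, as in TPM) or the genes (protein-coding only). Alternatives added after the data were seen required a counting interval that excludes 1, left out Smoc2 with the heart muscle and liver genes, or left out a library. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.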

Results

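Gene expression was measured by RNA sequencing in αTC1-6 cells, a mouse α-cell line that makes glucagon, 16 h after infection with an adenovirus for β-Gal, NIK or NIK(KA). Each group held 1 library. Sequencing depth was similar, with 18629668 counted reads for β-Gal, 15523580 for NIK and 16652922 for NIK(KA). Reads were found for 22186, 22519 and 22824 genes. The 5 most counted genes took 4.15%, 3.56% and 3.74% of the reads, and the mitochondrial gene mt-Co1 led in each library. Values are FPKM as deposited, and intervals are exact 95% intervals of a ratio of recovered reads, for counting error only. There were no replicates, so every difference below is one between single libraries.

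To check the labels, the transcript of the overexpressed kinase was examined first. Map3k14 (ENSMUSG00000020941, chromosome 11, 103219762 to 103267472 on GRCm38) had an FPKM of 5.35 in β-Gal, 8.42 in NIK and 12.1 in NIK(KA). It was 1.57-fold higher in NIK than in β-Gal (1.31 to 1.89) and 2.25-fold higher in NIK(KA) than in β-Gal (1.91 to 2.66). NIK was thus below NIK(KA), at a ratio of 0.698 (0.599 to 0.812). Both libraries labelled as overexpressing lay above the control. The labels do not give the species or extent of the viral coding sequence, so how far reads of the transgene enter these values is unknown.

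**Figure D1:**
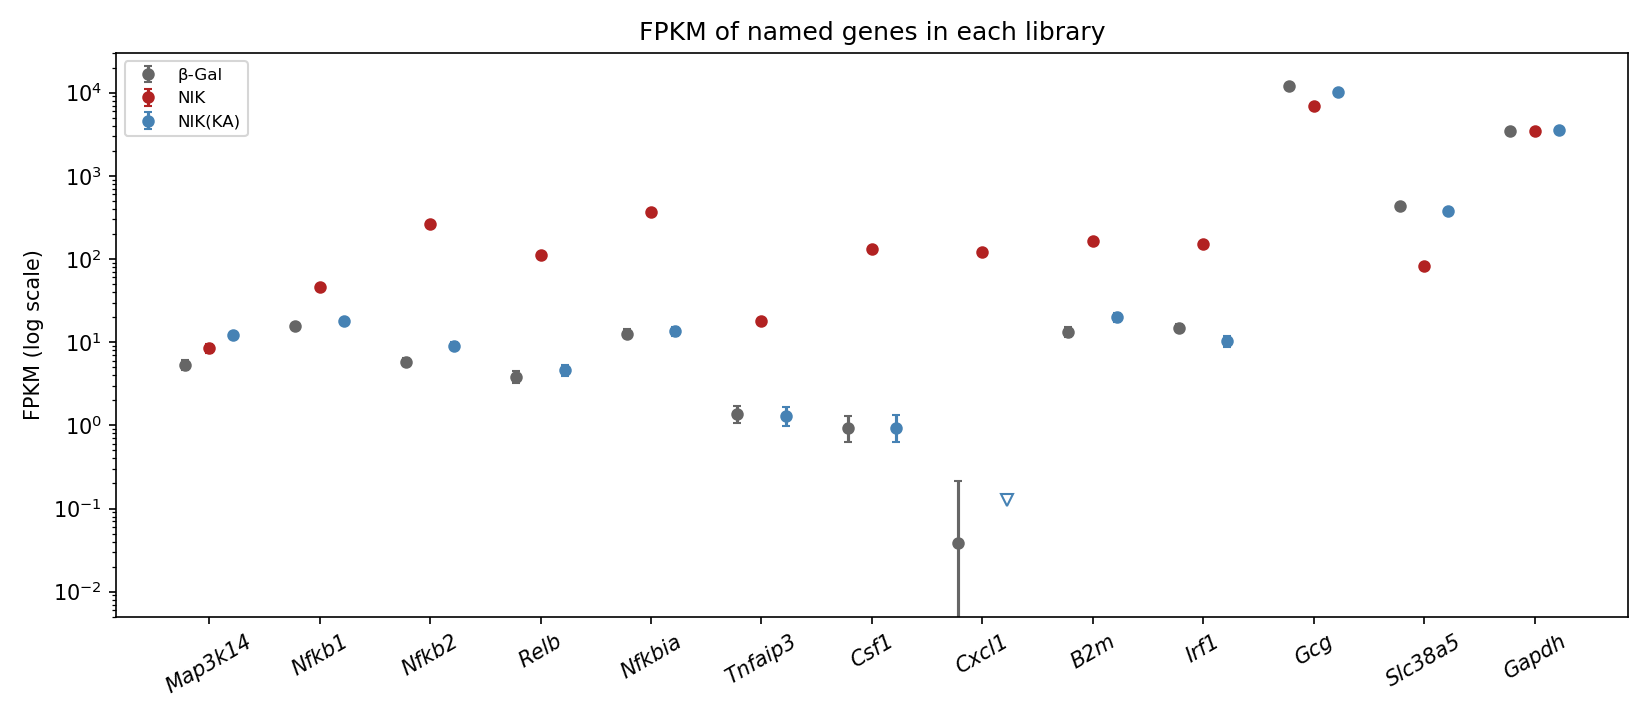
FPKM (log axis) of 13 named genes in the β-Gal, NIK and NIK(KA) libraries. Bars are exact 95% Poisson intervals of the reads, for counting error only, and the open triangle marks a library with 0 reads, drawn at the value of 3 reads. Nfkb2 was at 5.80 in β-Gal, 261 in NIK and 9.07 in NIK(KA), while Gapdh was at 3493, 3493 and 3563.

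The first comparison asked what active NIK does to the transcriptome of the α-cell line, with β-Gal as the viral control. In the NIK library 666 genes were at least 2-fold higher than in β-Gal and 192 were lower, out of 12950. Of the higher genes 561 were protein-coding, and 38 genes were at least 16-fold higher on the log2(FPKM + 1) scale. The higher genes with the largest differences were Spib, a transcription factor of B cells and dendritic cells, and Madcam1, an adhesion molecule of mucosal vessels. Spib had 9 reads in β-Gal and 5790 in NIK, 772-fold higher (406 to 1689). Madcam1 had 0 and 3104 reads, at least 1009-fold higher. Counting error alone gave a mean of 30.4 higher and 29.3 lower genes in simulated libraries, with at most 41 and 42.

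Genes of the NF-κB family and its feedback inhibitors were higher in NIK. Of the 14 measured genes of this list, 11 were at least 2-fold higher and 0 were lower, with a median log2 difference of 2.26 that lay above all 10000 random lists. Nfkb2, which encodes the p100 precursor of the non-canonical pathway, stands on chromosome 19 from 46304320 to 46312385. Its FPKM was 5.80 in β-Gal and 261 in NIK, 45.0-fold higher (40.4 to 50.3). Relb, the partner of the processed p100 product, was 29.4-fold higher (24.9 to 35.0). The inhibitors Nfkbia and Nfkbie were 29.5-fold (26.1 to 33.5) and 85.8-fold (67.2 to 111) higher. Tnfaip3, which encodes the deubiquitinase A20, was 13.3-fold higher (10.4 to 17.3), and Nfkb1 2.97-fold (2.73 to 3.23). Birc3 had 0 reads in β-Gal and 202 in NIK, at least 65.1-fold higher. Among 11 genes of the NIK and IKK regulators, 2 passed the rule. These were Traf3 and Birc2, whose proteins take part in NIK degradation, at 2.23-fold (2.07 to 2.40) and 2.13-fold (1.99 to 2.28) higher. That list's median was 0.25, at the 99.3 percentile.

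Chemokines, cytokines and surface receptors were higher in NIK as well. Only 8 of the 27 listed chemokines and cytokines passed the expression filter, and all 8 of these were higher, with a median of 4.11, above all random lists. The filter uses the mean of the 3 libraries, so it takes in genes detected mainly in NIK. With genes at 0 reads set to 3 reads, the median log2 ratio of that list was 7.13. Csf1, the growth factor of macrophages, was 144-fold higher (103 to 208). The neutrophil chemokine Cxcl1 had 1 read in β-Gal and 2688 in NIK, a ratio of 3226 (578 to 127461). Ccl2, the monocyte chemokine, had 0 and 472 reads, at least 153-fold higher. Of 14 listed adhesion and TNF-receptor-family genes 8 passed the filter, and of these 5 were higher and 0 lower, with a median of 3.83, above all random lists, or 7.85 as a ratio with 3 reads in place of 0. Cd40 had 0 and 777 reads, at least 252-fold higher. Vcam1 had 1 and 1319 reads, and Icam1 had 2 and 781.

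Antigen presentation and interferon-response genes were higher too. All 13 measured genes of MHC class I presentation were at least 2-fold higher in NIK, with a median of 2.61, above all random lists. B2m, the light chain of class I molecules, was 12.4-fold higher (10.8 to 14.4). The heavy-chain gene H2-K1 was 10.9-fold higher (9.55 to 12.6), though some of its reads may match other H2 genes. The peptide-loading gene Tapbp was 10.4-fold higher (9.49 to 11.5). Of 23 listed interferon-response genes 11 passed the filter, and of these 9 were higher and 0 lower, with a median of 2.26, above all random lists, or 2.92 with 3 reads in place of 0. Irf1 was 10.4-fold higher (9.23 to 11.7), and Ddx58, which encodes the RNA sensor RIG-I, 26.4-fold (17.6 to 41.6).

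**Figure D2:**
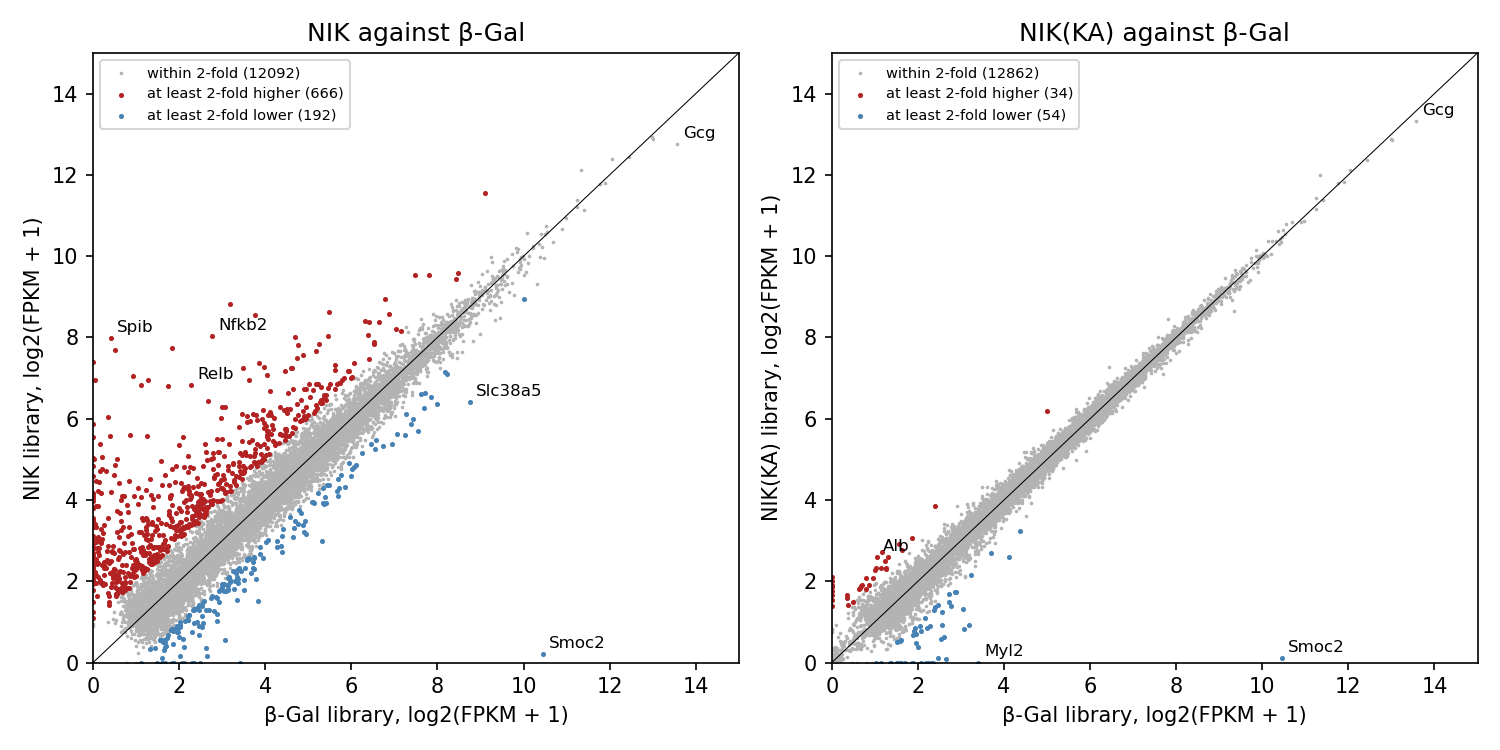
Level of each of the 12950 genes, as log2(FPKM + 1), in the NIK library (left) and the NIK(KA) library (right) against the β-Gal library. Coloured points differ by at least 2-fold: 666 higher and 192 lower in NIK, 34 higher and 54 lower in NIK(KA).

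The genes of α-cell identity showed few 2-fold differences. Of 19 measured, 1 was higher and 1 was lower in NIK than in β-Gal. The lower gene was Slc38a5, a glutamine transporter of α cells, whose FPKM was 430 in β-Gal and 83.5 in NIK, 5.15-fold lower (4.91 to 5.40). The higher gene was Loxl4, with 2 reads in β-Gal and 106 in NIK. The list's median of -0.12 lay at the 8.76 percentile, within the random lists. It lay below them with TPM or upper-quartile scaling, at -0.26 and -0.29, and with a mean FPKM of at least 5, at -0.38. Gcg, the glucagon gene on chromosome 2 from 62474530 to 62483650, was at 12093 FPKM in β-Gal, 6955 in NIK and 10197 in NIK(KA). It took 1.01% of the reads in β-Gal (1.01 to 1.02), 0.581% in NIK (0.578 to 0.585) and 0.852% in NIK(KA) (0.848 to 0.857), by exact binomial intervals. In NIK it was 1.74-fold below β-Gal (1.73 to 1.75), a difference of -0.80 that does not meet the 2-fold rule.

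Other lists of the secretory cell and of its metabolism lay to one side of the random lists with few genes past the rule. Of 22 secretory-granule genes, only Vgf was higher, 3.30-fold (3.22 to 3.38), and 0 were lower, while the list's median was -0.20, at the 0.39 percentile. No gene of 9 for excitability channels passed the rule, and the median was 0.29, at the 98.4 percentile. With a pseudocount of 5 that median was 0.14, within the random lists. Medians below the random lists, each at or under the 0.33 percentile, were found for oxidative phosphorylation (-0.29), cholesterol synthesis (-0.24) and glycolysis (-0.25). Hexokinase 2 (Hk2) and neuronal enolase (Eno2), of 16 glycolysis genes, were higher against that median, at 4.43-fold (3.17 to 6.30) and 2.14-fold (2.08 to 2.20). The 24 ribosomal protein genes had a median of 0.11, at the 99.2 percentile. The 14 housekeeping genes had a median of 0.03, and of -0.01 with upper-quartile scaling, both within the random lists. Medians within the random lists were also those of Nrf2 targets (0.13) and of mitochondrially encoded genes (-0.04).

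Stress and growth genes differed in both directions. Of 16 apoptosis and p53 target genes, 4 were higher and 1 lower, with a median of 0.71, above all random lists. Gadd45b was 5.11-fold higher (4.44 to 5.90) and Bbc3, a p53 target that promotes apoptosis, 2.54-fold (2.26 to 2.86), whereas Gadd45a was 3.15-fold lower (2.93 to 3.40). Immediate early genes had 3 higher members, Ier5, Junb and Myc, and 2 lower ones, including Fosl2, while the median of all 14 was -0.33, at the 0.09 percentile. With a pseudocount of 5 it was -0.11, within the random lists. Ier5 was 15.8-fold higher (14.1 to 17.7) and Fosl2 2.46-fold lower (2.32 to 2.60). The unfolded protein response list had 1 higher gene of 18, Ppp1r15a, and a median of -0.27, at the 0.04 percentile. Of 25 cell cycle genes 0 were higher, and Ccnd2 was 2.43-fold lower (1.98 to 2.99), with a median of -0.05, within the random lists.

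Several of the lower genes in NIK were detected mainly in the β-Gal library. Smoc2, a secreted matrix protein gene on chromosome 17 from 14279506 to 14404790, had 74005 reads in β-Gal, 0.397% of that library. It had 7 reads in NIK and 4 in NIK(KA). The heart muscle genes Myl2, Myl3, Mb, Actc1 and Myh6 were also among the 10 lower genes, with 68 to 102 reads in β-Gal and 0 to 4 in NIK. Without Smoc2 and the heart muscle and liver genes, 664 genes were higher and 185 lower. Of the remaining top genes, Scgn, which encodes the calcium-binding protein secretagogin, was 5.56-fold lower (4.37 to 7.16). Ddc, which encodes the aromatic amino acid decarboxylase, was 3.63-fold lower (3.38 to 3.90).

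Most markers of other cells lay under the expression filter. Ins2 and Sst, the genes of β and δ cells, had 0 reads in each library, which allows up to 3 reads. Of 14 markers of other islet cells 4 passed the filter and 0 met the rule in NIK against β-Gal, with a median of -0.01. Of 17 markers of leukocytes, stroma, endothelium, duct and acinus, 4 passed the filter. Sox9, a duct factor, was at 3.15 FPKM in β-Gal, 8.69 in NIK and 2.63 in NIK(KA). It was 2.76-fold higher in NIK than in β-Gal (2.37 to 3.22). The collagen gene Col1a2 was 3.80-fold lower in NIK (2.49 to 5.99), and the median of the 4 was 0.22. The leukocyte gene Ptprc, named after its values were seen, was at 0 FPKM in β-Gal and NIK. Gapdh had a ratio of 1.00 between NIK and β-Gal (0.988 to 1.01), and Actb was 1.40-fold higher (1.35 to 1.45).

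**Figure D3:**
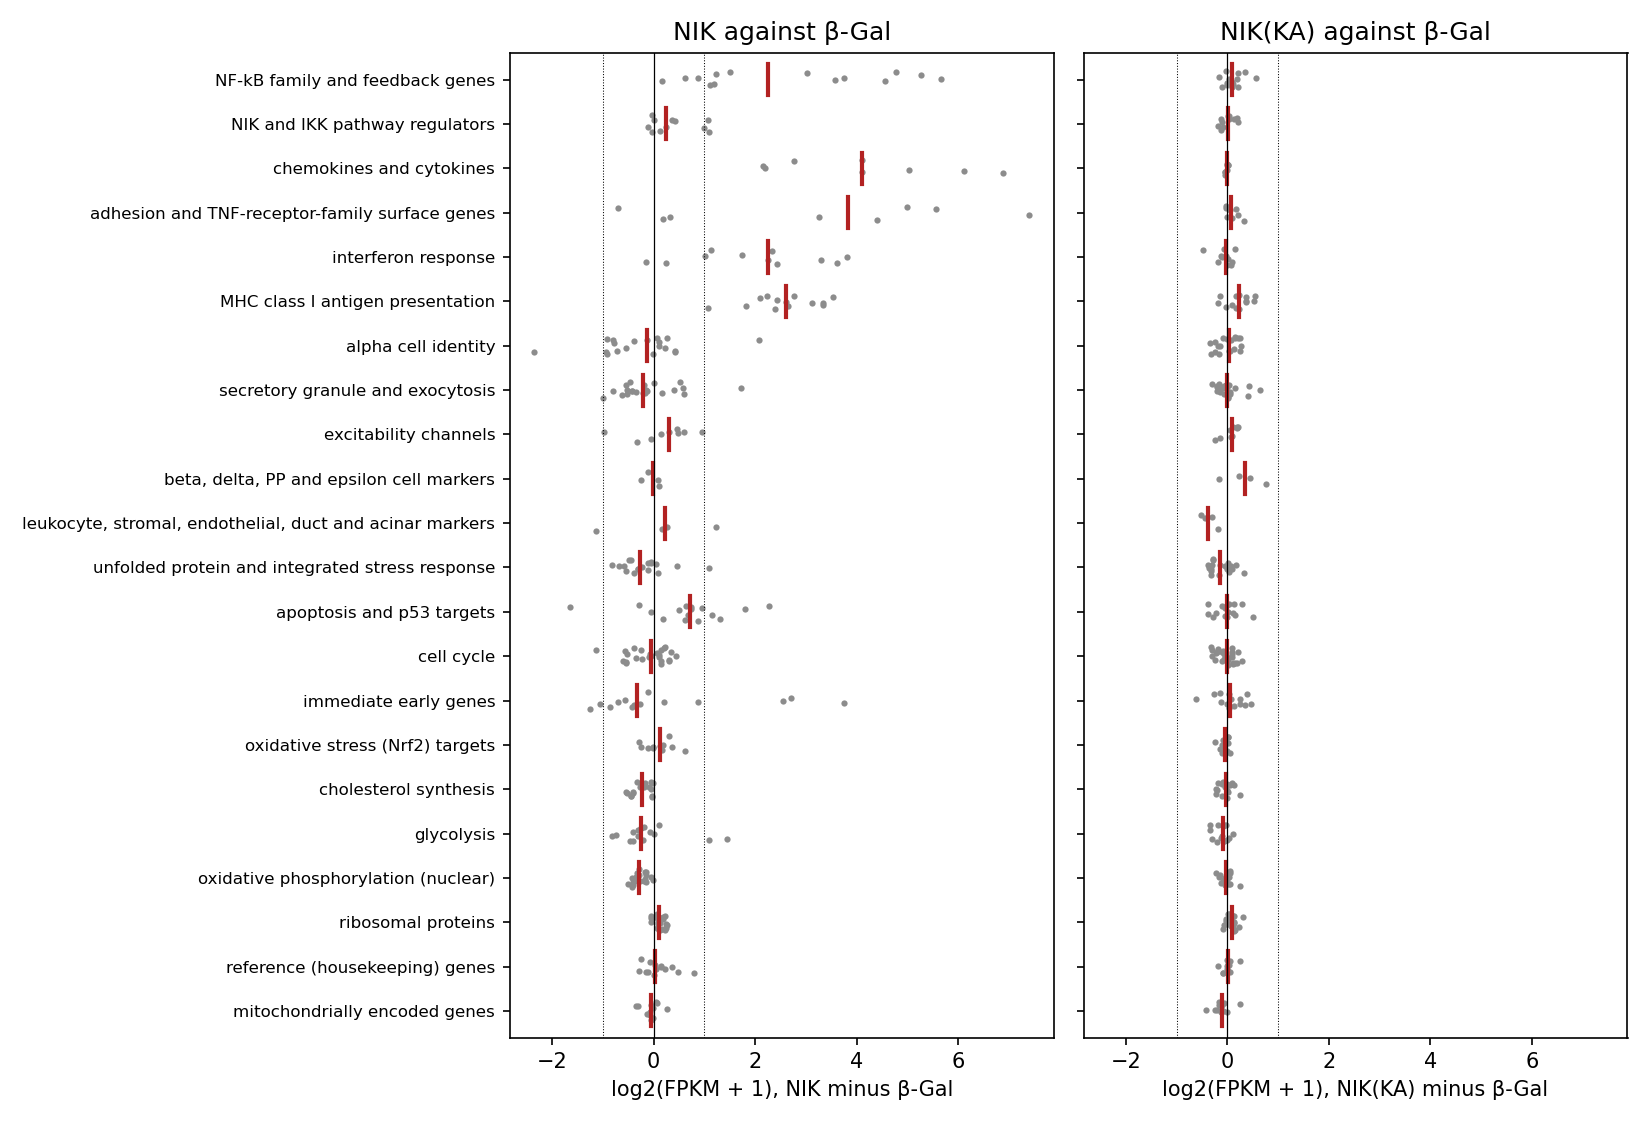
Difference of log2(FPKM + 1) from β-Gal for the members of each gene list past the filter, in NIK (left) and NIK(KA) (right). Each point is a gene, the red bar is the list's median, and the dotted lines mark the 2-fold rule. The medians of chemokines and cytokines were 4.11 in NIK and 0 in NIK(KA).

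The second comparison asked what NIK(KA) does in the same cells. Few genes differed, with 34 at least 2-fold higher and 54 lower than in β-Gal. Only 7 and 8 of these were protein-coding. The lower coding genes were Smoc2, 6 heart muscle genes (Myl2, Mb, Myl3, Actc1, Tnni3 and Myh6) and Spink4. The higher ones with a known symbol were Alb, Apoa2, Il17f, Neurl3, Amy1 and Dll3. Alb, the liver gene for serum albumin, was 4.66-fold higher (2.76 to 8.29), and the apolipoprotein gene Apoa2 2.80-fold (1.72 to 4.70), with 75 and 60 reads in NIK(KA). Neurl3, a ubiquitin ligase gene, was 7.05-fold higher (3.59 to 15.4), with 10 reads in β-Gal, 63 in NIK(KA) and 1924 in NIK. Genes past the rule were short and had few reads, with a median length of 91.5 bases for the higher and 107 for the lower genes, and a median of 8 and 8.5 reads over both libraries. In 23 and 32 of them the counting interval included 1. Counting error alone gave a mean of 29.6 higher and 29.3 lower genes, with at most 46 and 48, so the 34 higher genes lay within the simulated range and the 54 lower genes above it. Without Smoc2 and the heart muscle and liver genes, a choice made after the data were seen, 47 genes were lower, within the simulated range, which 1 of 100 simulated sets reached.

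On the log2(FPKM + 1) scale, which understates the differences of low genes, the genes that were higher in NIK showed little difference in NIK(KA). No gene of the NF-κB, chemokine, adhesion, interferon or MHC class I lists passed the rule in NIK(KA) against β-Gal. The MHC class I median was nevertheless 0.22, above all random lists, and Nfkb2 was 1.57-fold higher (1.36 to 1.81). Relb was at a ratio of 1.20 (0.947 to 1.51) and Nfkbia at 1.07 (0.901 to 1.28), both intervals including 1. Medians below the random lists were found for the unfolded protein response (-0.15), glycolysis (-0.09) and mitochondrially encoded genes (-0.12). Markers of other islet cells (0.34) and of leukocytes and other cells (-0.37) lay above and below them, each over 4 genes, and within them when genes were not filtered. The islet markers were within them as TPM as well (0.22). Gcg was 1.19-fold lower (1.18 to 1.19).

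Both comparisons share the β-Gal library. In all, 32 genes were 2-fold from β-Gal in the same direction in NIK and NIK(KA), 11 of them higher and 21 lower. Independent lists would share 1.75 and 0.801. Libraries simulated with counting error alone and a shared control gave a mean of 18.6 and at most 28. In these simulated libraries NIK was unchanged too, with a mean of 30.4 higher and 29.3 lower genes against 666 and 192 observed. They therefore do not show how many genes a changed NIK library would share with NIK(KA). Without Smoc2 and the heart muscle and liver genes, a choice made after the data were seen, 25 were shared. Leaving genes out lowers the count by its construction. Of 100 simulated sets, 9 reached 25.

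The third comparison set NIK against NIK(KA), which leaves out the β-Gal library. It gave 657 higher and 142 lower genes, 530 and 91 of them protein-coding. Spib, Madcam1, Cxcl1, Srgn, Csf1, C3, Cd40, Igsf9, Nfkbie and Stap2 were the 10 highest. Nfkb2 was 28.8-fold higher in NIK (26.3 to 31.6) and Relb 24.6-fold (20.9 to 29.1), although Map3k14 was lower in NIK than in NIK(KA). All 13 MHC class I genes and 11 of 14 NF-κB genes were higher, with medians of 2.31 and 2.23. For the 8 chemokine and cytokine genes and the 11 interferon-response genes, 8 and 9 were higher, with medians of 4.13 and 2.11. Each of these medians lay above all random lists. The medians of adhesion genes (3.76), apoptosis and p53 targets (0.68) and NIK and IKK regulators (0.37) also lay above the random lists.

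The genes lower in NIK than in NIK(KA) were of several kinds. Slc38a5 was 4.53-fold lower (4.31 to 4.76) and Scgn 4.49-fold (3.51 to 5.82). The potassium channel genes Kcnc4 and Kcnk16 were 5.81-fold (4.58 to 7.46) and 4.99-fold (3.62 to 7.03) lower. They are not in the excitability list, of which 0 of 9 genes were lower, with a median of 0.19, at the 95.5 percentile. That median lay above the random lists with no filter (0.12) or a mean FPKM of at least 5 (0.29). Cck, the gene of the peptide cholecystokinin, was 5.48-fold lower (2.56 to 13.4) on 8 and 47 reads. Chga, which encodes the granule protein chromogranin A, was 2.08-fold lower (2.03 to 2.13). The α-cell identity list had a median of -0.23, at the 0.41 percentile, and Gcg was 1.47-fold lower (1.45 to 1.48). Alb was among the 10 lower genes, with 6 reads in NIK and 75 in NIK(KA), and it lies with the other liver genes found in NIK(KA). The secretory-granule median was -0.18, at the 1.72 percentile, and within the random lists with a pseudocount of 5 (-0.17) or no filter (-0.14). Medians below the random lists were also found for immediate early genes (-0.47), cholesterol synthesis (-0.27) and oxidative phosphorylation (-0.23). Markers of other islet cells (-0.42), over 4 genes, lay below them too, but within them with no filter (-0.09), a mean FPKM of at least 5 (-0.36) or TPM (-0.38).

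Against both other libraries at once, 564 genes were higher in NIK and 86 were lower, of which 495 and 65 were protein-coding. Counting error alone gave means of 7.64 and 14.96. Between NIK(KA) and β-Gal, 560 of the 564 and 86 of the 86 lay within 2-fold on the log2(FPKM + 1) scale, with median differences of 0.04 and -0.12. Genes near 0 in both libraries meet that almost by construction. Srgn, with 6 reads in β-Gal and 20 in NIK(KA), was 3.73-fold higher (1.44 to 11.3) but had a difference of 0.86. Without the NIK(KA) library the lower count was 192, and without β-Gal it was 142, by construction the counts of the single comparisons that remain.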

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

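Of the settings below, the counting interval, leaving out Smoc2 with the heart muscle and liver genes, and the libraries left out were chosen after the data were seen. No paired analysis was possible because each group has 1 library, and no replicate could be left out. No result called higher or lower changed sign. The housekeeping median of NIK against β-Gal, 0.03, was -0.01 with upper-quartile scaling. Median-ratio and upper-quartile scaling kept every count of genes within 1.5 times, and so did leaving out Smoc2 with the heart muscle and liver genes. That last choice, however, brought the lower genes in NIK(KA) from 54 to 47 and the shared genes from 32 to 25. Both lie in the range that counting error alone gave, the 47 near its top, but leaving genes out lowers both counts by its construction. The simulated libraries also held NIK unchanged, so their range does not settle the 25. Of 100 simulated sets, 1 reached the 47 lower genes and 9 reached the 25 shared genes. Counts that moved by more under the other settings are given here, in the order NIK against β-Gal, NIK(KA) against β-Gal, NIK against NIK(KA), NIK against both, and genes shared in direction.

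With a pseudocount of 0.1, lower genes were 357, 128 and 305, higher genes in NIK(KA) 119, lower than both 212, and shared 105. With a pseudocount of 5, higher genes were 357, 1 and 335, lower genes 54, 6 and 34, higher and lower than both 309 and 28, and shared 4; the Map3k14 difference between NIK(KA) and β-Gal was 0.72, below the 2-fold rule. A pseudocount shrinks low genes by its construction. Without a filter, NIK(KA) had 108 higher and 114 lower genes, NIK 217 lower than NIK(KA), and shared genes were 82; 1 list lay above the random lists in NIK(KA). With a mean FPKM of at least 5, fewer genes were tested, with 392, 4 and 368 higher, 106, 6 and 69 lower, 337 higher than both and 5 shared. Scaled as TPM, NIK(KA) had 99 higher and 115 lower genes and 1 list above the random lists. NIK then had 233 lower than NIK(KA) and 136 lower than both, and 88 were shared. This scaling raises all values, so the filter takes in more low genes and the pseudocount of 1 weighs less. These effects were not separated. Among protein-coding genes, 120, 8 and 91 were lower, 7 were higher in NIK(KA) and 9 were shared. With a counting interval that excludes 1, NIK(KA) had 11 higher and 22 lower genes, and 12 were shared. Lower genes in NIK were 142 without β-Gal and 192 without NIK(KA), by construction the counts of the single comparisons that remain. Beyond what is said of low genes, the cause was not tested.

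Of the list medians recomputed, 454 moved by less than their counting interval and 71 by more. Of the single genes named, 701 and 114 did. Depth limits the genes with few reads, which make up most of the NIK(KA) calls.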

Other observations

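The tests of Smoc2 against the heart muscle reads, of the counting intervals of Smoc2 and the heart muscle genes, of the protein-coding genes of NIK(KA), of the median over all genes, of genes with 10 or more reads in the complement, MHC class II and thymic lists, and of carried-over reads were chosen after the results they measure were seen, and so were the genes named below that the naming rule does not give.

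Single genes of complement and the acute phase were among those with a large difference in NIK. C3, the central complement component, had 36 reads in β-Gal, 35 in NIK(KA) and 2924 in NIK, 89.6-fold above NIK(KA) (64.3 to 129). Saa3 and Lcn2, acute-phase genes, each had 2 reads in β-Gal and 347 and 361 in NIK, with ratios of 208 (57.2 to 1726) and 217 (59.5 to 1796). The complement protease gene C1ra had 0 and 220 reads, at least 71.0-fold higher, and Crp, the gene of C-reactive protein, 0 and 182, at least 58.6-fold. C1qa was 6.47-fold higher (4.75 to 8.96), but C1qb and C1qc, in the list tested below, had 0 reads in NIK. Nos2, the inducible nitric oxide synthase gene, had 0 reads in both other libraries and 712 in NIK, at least 231-fold above β-Gal. Serpina1a and Serpina1b, copies whose reads may match both, were 10.7-fold (7.93 to 14.7) and 24.8-fold (15.1 to 43.9) higher.

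The higher genes led to the hypothesis that complement and acute-phase genes are higher as a group, tested on 20 others that had not been looked at. Of these only 2 passed the filter, and 0 were 2-fold higher in NIK than in each other library. That meets the rule set in advance against the hypothesis. After the result was seen, the test was judged to leave the question open, because the genes that led to the hypothesis were left out and 2 genes are too few. Of the 6 genes of the list with 10 or more reads, 1 was 2-fold above both other libraries in NIK. Cd74, the invariant chain of MHC class II, had 3 reads in β-Gal, 3 in NIK(KA) and 830 in NIK, so 13 MHC class II genes were tested. Of the 4 past the filter 1 was higher, the regulator Rfx5, which leaves the question open. Of the 7 with 10 or more reads, 3 were 2-fold above both others in NIK. Besides Rfx5 these were Ciita and H2-Aa, both under the filter. Ciita had 3 reads in β-Gal, 39 in NIK and 7 in NIK(KA), and H2-Aa 0, 16 and 0. Aire, a regulator of the thymic medulla, was 18.1-fold higher than in β-Gal (11.2 to 31.0). Of 17 genes listed for medullary thymic epithelium 2 passed the filter, and 0 were higher. These 2, Hdac3 and Ctsl, are broadly expressed and so not particular to that tissue. This also meets the rule set in advance against a wider thymic program, and was likewise judged after the fact to leave it open. Of the 5 with 10 or more reads, 2 were 2-fold above both others in NIK.

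Single genes known from immune cells, such as Spib, Cd40 and Cd74, were higher in NIK, and 2 technical explanations were tested. Leukocytes in the NIK culture would bring their abundant transcripts, but the median FPKM of 22 leukocyte genes was 0.116 in NIK, below 4.61, the bound set in advance from the Cd40 level. Of the 9 with 10 or more reads, 3 (Cd4, Lcp1 and Cd37) were 2-fold above both other libraries. The highest, Cd4, reached 5.59, and 2 of the 22 were at an FPKM of 1 or more in both other libraries. A few genes taking a larger share of the reads in a library would shift all other genes alike, but the median log2 difference over all 12950 genes was -0.018 against β-Gal and -0.032 against NIK(KA). Median-ratio scaling gave 583 genes higher in NIK than in both others, against 564, which adds nothing, since it moved those medians by only 0.015 and 0.030. The leukocyte median and the median over all genes argue against these explanations as the whole cause. An effect of NIK in the α-cell line is a hypothesis that stays open, since a single library carries it.

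The genes past the 2-fold rule between NIK(KA) and β-Gal may have several sources. Libraries simulated with counting error alone gave on average 67.0% as many as the 88 observed, and 55 of the 88 had an interval that included 1, so counting error is a candidate explanation for most of the short genes. It gave a mean of 2.62 and at most 6 protein-coding genes, below the 15 observed. Leaving out Smoc2 and the heart muscle and liver genes, chosen after the data were seen, lowers the observed count by its construction. The 6 that then remain were reached by 5 of 100 simulated sets. For Smoc2 and the 6 heart muscle genes counting error is excluded, since the lowest interval bound was 2.66-fold above the other libraries. Of 22 further heart muscle genes, 8 of the 16 with 10 or more reads were at least 2-fold above both others in β-Gal. In NIK 0 were, and in NIK(KA) 1. Tnnt2 had 59 reads in β-Gal, 1 in NIK and 3 in NIK(KA), whereas Ryr2 had 646, 322 and 494. The rule set in advance asked for most of the 16, and 8 is neither most nor few enough to count against. By that rule it stays undecided whether heart RNA or reads entered the β-Gal library. Of the 22, 5, with Ryr2 among them, were at an FPKM of 1 or more in both other libraries, where a small addition would be hidden. These 5 all lie outside the 8. Smoc2 had 44.4 times the reads of all 28 heart muscle genes together, which argues against the same source. Of 23 further liver genes, 6 of the 11 with 10 or more reads were 2-fold above both others in NIK(KA), against 0 in β-Gal and 3 in NIK, consistent with a trace of liver RNA or reads in NIK(KA), where Alb reached 5.01 FPKM; 2 of the 23 are at an FPKM of 1 or more in both other libraries. The source of Smoc2 was not identified, and no biological explanation of these genes was tested.

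Neurl3 (7.05-fold, 3.59 to 15.4), Nfkb2 (1.57-fold, 1.36 to 1.81) and the MHC class I list (median 0.22) were higher in NIK(KA) than in β-Gal, and reads of the NIK library carried over into NIK(KA) could give that. In 9 genes with 0 reads in β-Gal and at least 300 in NIK, the level in NIK(KA) was 0.210% of that in NIK (0.127 to 0.329). In NIK(KA), 6 of the 9 had 0 reads. Of the 19 reads there, 15 were those of Mmp9, so the pooled share rests mostly on that gene, which its interval does not show. The excess of Neurl3 over β-Gal was 2.62% of its NIK level, 12.5 times that share. The median excess of the 13 MHC class I genes was 2.85%, 13.5 times that share, with 10 of the 13 above β-Gal. Carried-over reads are therefore too few for either. An effect of the mutated kinase, or a difference between single cultures, remains possible and was not tested.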
